A study of Mus musculus with 48 samples.

How the data were processed

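The midbrain of 48 mouse pups was profiled by RNA-seq. The values used here are the read counts per gene that the authors deposited as a single matrix, whole numbers that had not been normalized. Per the labels' protocols, RNA was extracted with a Zymo Quick-DNA/RNA kit, libraries were made from 200 ng of total RNA with the KAPA mRNA HyperPrep kit, and paired-end reads of 50 bp were sequenced on a NovaSeq instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and cutadapt 2.8 and aligned with STAR 2.5.3a to GRCm38. The annotation release, the counting mode and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The matrix held 54752 gene entries and 4 entries that name no gene. Those 4 took a mean of 4.71% (unmapped), 8.06% (multimapping), 9.90% (no feature) and 1.20% (ambiguous) of all counts per library and were left out of library sizes and tests. Gene IDs were matched to symbols with a supplied table (54723 matched, 29 not). Positions come from the GENCODE mouse release 21 on GRCm38, supplied as the reference here.

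Group, sex, dam (litter), library batch and RNA integrity number (RIN) were taken from the labels. What order the dam numbers follow is not given in the sources used here, so late or later dams means only higher numbers. Counts per gene summed to between 26108700 and 35556100 per library. No 2 libraries were copies of each other: over all 1128 pairs, the smallest ratio of squared count differences to sampling noise was 11.3. Litter mates were paired by the dam in the labels. Their deviations from the group means had a median correlation of -0.01 over 42 pairs, against -0.03 for pairs of different litters, and the litter remained the replicate because the injection was given to the dam.

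The main model used the sums of the 35 libraries of batches 1 to 3 per litter, 19 in all (8 PBS, 6 MCMV and 5 MHV68). Batch 4 holds no PBS pup and batch 5 only 3 MCMV pups with the lowest RIN values (mean 7.40, against 9.07 to 9.37 in batches 1 to 4). Genes were filtered with filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with robust estimation, with the group, the batch and whether the litter sum held only a female as terms. All 3 groups were fitted together and shared 1 estimate of the spread. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 in each comparison. Standard errors of log2 fold changes are the absolute fold change divided by the square root of the F statistic. Means and SDs in CPM are over litter sums, or over pups where pups are named. The same contrasts were fitted within each sex on 1 pup per litter with the batch as a term. Males and females were compared in the 16 litters with both sexes, with the litter as a block, and interaction terms tested whether the sex difference depended on the infection.

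42 gene lists (dopamine and other neurons, glia, vessels and meninges, neighbouring brain regions, blood and immune cells, immune responses, stress responses, metabolism, signalling) were tested on log2 CPM of the litter sums (prior count 2) with camera of limma 3.58.1. Camera was run with the preset inter-gene correlation of 0.01 and again with the correlation estimated, and fry was run as another test, with Benjamini-Hochberg adjustment over the 42 lists of a comparison. A list needed at least 5 tested members. Fold changes that share the PBS litters were compared with 20 simulations of unchanged groups and with 24 splits of the PBS litters. Where groups are compared in a single value, exact two-sided permutation tests were used.

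The lists, the designs, the other settings and the rule for named genes were fixed before the data were examined. The rule names all genes that pass if at most 16 do, and otherwise the 8 largest rises and 8 largest falls among genes with a mean of at least 1 CPM. If fewer than 6 pass, the 5 smallest p values of each direction are named as not passing. It adds a panel of 10 dopamine genes in every comparison, the 3 members with the smallest p of each list that camera calls with the preset correlation, and the 5 smallest p values that pass in each test within a sex or of sex. Some genes that this rule names are not reported here. Predicted genes are counted and not named, which left out Gm29650 among the sex differences. Other genes named as the members of a list that passed, and Lcn2 in males, were chosen after their values were seen.

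Each test was run on simulated counts with 200 changed genes per fold size before use. In MHV68 against PBS it recovered 12.5% of genes changed 1.2-fold, 69.5% at 1.5-fold, 90.5% at 2-fold and 98% at 4-fold, and in MCMV against PBS 22.5%, 71%, 94% and 99.5%. In MCMV against MHV68 the shares were 11.5%, 64.5%, 93.5% and 100%. Within a sex, genes changed 1.5-fold were recovered in 58.5% (MCMV females), 52% (MHV68 females), 42.5% (MCMV males) and 34.5% (MHV68 males) of cases, and sex interactions of 2-fold in 56% (MCMV) and 53% (MHV68). A list shifted 1.3-fold was called in 4 of 4 simulations with both correlations, with 0 other lists called at the preset correlation. The simulated genes varied independently of each other, whereas the correlation estimated in the data was 0.584 for the heat shock list and 0.925 for the ribosome list. The simulations therefore do not show how often camera calls or misses a list by error in these data.

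Other settings fixed at that time were the size factors of DESeq2 (RLE) in the same fit, the Wald test of DESeq2 1.42.0, no filter, a filter at a mean of 1 CPM, all 48 libraries as separate samples, all 48 in limma-voom with the litter as a block, all 48 summed per litter, no batch term, no term for female-only litters, the mean RIN of the litter as a covariate, 1 surrogate variable from sva 3.50.0, and each litter left out in turn. Settings added after the data were seen were 2 components of dissection (the first principal components of marker genes of neighbouring regions), the dam's number as a covariate, a fit without PBS litters 6 and 26, a fit of the lists without PBS litter 1, and a fit of only the litters of dams numbered 9 and above.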

Results

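RNA was sequenced from the midbrain of 8-week-old mice whose mothers had been injected at embryonic day 8.5 with murine cytomegalovirus (MCMV, a betaherpesvirus), with MHV68 (a murine gammaherpesvirus) or with phosphate-buffered saline (PBS) as the control. The series holds 48 libraries, 1 per pup. They are 15 PBS pups of 8 litters (8 females and 7 males), 18 MCMV pups of 6 litters (9 females and 9 males) and 15 MHV68 pups of 5 litters (9 females and 6 males). Counts assigned to genes ran from 26108700 to 35556100 per library, given to 6 digits, and overlapped between the groups. The female-specific transcript Xist averaged 284 CPM (counts scaled to the library total) in the 26 females and 2.35 CPM in the 22 males, and the Y-linked Ddx3y averaged 0.316 CPM in females and 68.5 CPM in males, so no library went against its sex label. Because the dam received the injection, the litter was the replicate. The 35 libraries of batches 1 to 3, the batches with pups of all 3 groups, were summed per litter, which gave 8 PBS, 6 MCMV and 5 MHV68 litters. Batch 4 (4 MCMV and 6 MHV68 libraries) and batch 5 (3 MCMV libraries) held no PBS pup and did not enter the litter sums. They were used where all 48 libraries or all pups are named.

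The tissue pieces differed in content between pups of every group. Th, the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214.11; GRCm38 chromosome 7, 142892752 to 142931128), ranged from 3.76 to 150 CPM over the 48 libraries, with a median of 54.8 CPM. Brother and sister of a litter differed in Th by a median of 0.75 on the log2 scale over 16 pairs. Gabra6, a marker of cerebellar granule cells, ranged from 0 to 677 CPM, and Ttr, the main transcript of the choroid plexus, from 1.75 to 1845 CPM. In the litter sums, Gabra6 averaged 19.7 ± 37.9 CPM in PBS (SD, n = 8), 1.35 ± 2.75 CPM in MCMV (SD, n = 6) and 1.56 ± 2.69 CPM in MHV68 (SD, n = 5).

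The comparison of MHV68 with PBS asked whether gammaherpesvirus injection of the dam early in gestation was followed by a different midbrain transcriptome in the adult offspring. Among named genes with a mean of at least 1 CPM, the steepest fall was in Plin4, which codes for a coat protein of lipid droplets (ENSMUSG00000002831.13; GRCm38 chromosome 17, 56100591 to 56109803). Plin4 was at 5.31 ± 1.36 CPM in PBS litters (SD, n = 8) and 2.12 ± 0.0734 CPM in MHV68 litters (SD, n = 5), a log2 fold change of -1.34 (SE 0.215). Tnfrsf12a, the receptor of the cytokine TWEAK (ENSMUSG00000023905.15; chromosome 17, 23675445 to 23677468), was at 11.5 ± 3.53 CPM in PBS and 5.93 ± 1.11 CPM in MHV68 and fell by 1.05 on the log2 scale (SE 0.174). The small heat shock protein gene Hspb1 fell by 0.84 (SE 0.195) and the cell cycle inhibitor gene Cdkn1a by 0.77 (SE 0.178). Srarp, a regulator of steroid receptors, fell by 0.73, the nuclear matrix protein gene Banp fell by 0.66, and Pglyrp1, a peptidoglycan recognition protein gene, fell by 0.64. Ppp1ccb, a copy of a protein phosphatase gene that may share reads with its parent and is therefore uncertain, fell by 0.61.

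Among the genes above that level, the rises were smaller than the steepest falls. Slc7a11, the cystine and glutamate exchanger (ENSMUSG00000027737.10; GRCm38 chromosome 3, 49892526 to 50443614), was at 41.7 ± 7.64 CPM in PBS litters (SD, n = 8) and 66.9 ± 8.49 CPM in MHV68 litters (SD, n = 5), a log2 fold change of 0.69 (SE 0.127). Gpam, which catalyses the first step of triglyceride synthesis, rose from 38.1 ± 5.40 to 66.5 ± 15.5 CPM (log2 fold change 0.71, SE 0.132). Slc9a7, a sodium and proton exchanger of the Golgi, rose by 0.78, the synaptotagmin gene Syt10 by 0.71, the interferon-inducible helicase gene Ddx60 by 0.68, the cation channel gene Trpc5 by 0.65 and the ABC transporter gene Abca6 by 0.63. Pcdha7 rose by 0.67, but its reads can be shared with the other clustered protocadherins, so its value is uncertain. In all, 286 of 20647 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 159 higher and 127 lower in MHV68. Their median absolute log2 fold change was 0.33, 26 of them were predicted or unnamed genes, and the adjusted p of the 16 genes named here and above ran from 0.0178 for Plin4, Tnfrsf12a and Abca6 to 0.0491 for Pcdha7.

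**Figure D1:**
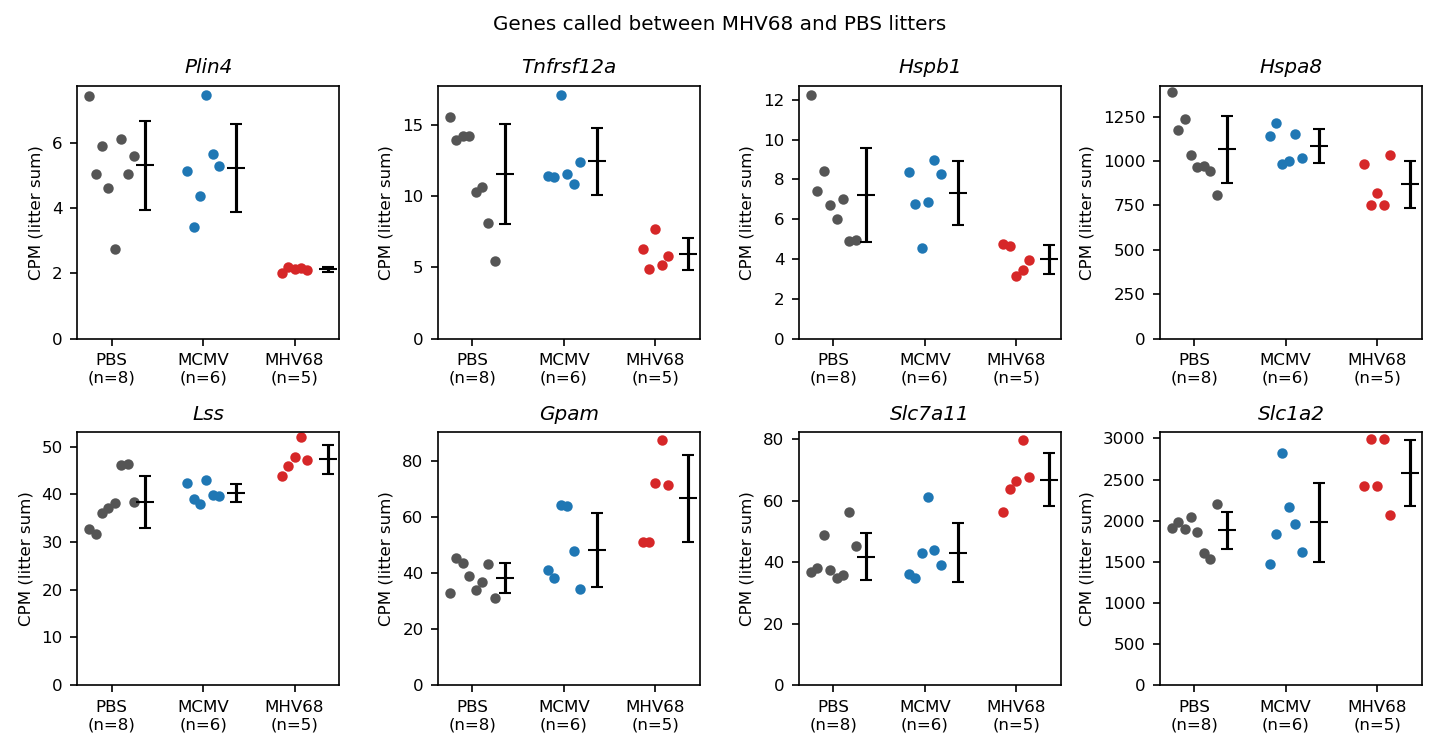
Expression in CPM (vertical axes) of 8 genes in each litter sum of batches 1 to 3, by group of the dam (8 PBS, 6 MCMV and 5 MHV68 litters), with the mean and SD of each group as bars. Plin4 averaged 5.31 CPM in PBS, 5.22 CPM in MCMV and 2.12 CPM in MHV68, and Slc7a11 41.7, 43.0 and 66.9 CPM.

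Genes of the heat shock and unfolded protein responses were lower in MHV68 litters as a group. All 18 tested members lay below PBS, with a median log2 fold change of -0.37. The mean of the list, in log2 CPM relative to the mean of the 19 litters, ran from -0.410 to -0.145 in MHV68 litters. In PBS litters it ran from -0.230 (litter 26, within the MHV68 range) to 0.653 (litter 1). The separation came from batches 1 and 2, where PBS litters lay at 0.109 to 0.653 and MHV68 litters at -0.410 to -0.145. In batch 3 the only MHV68 litter, litter 18, lay at -0.186, among the PBS litters of that batch (-0.230 to -0.0821). Without PBS litter 1 the list was still called by camera with the preset correlation (adjusted p = 3.1e-10). 5 members fell: Hspb1, the transcription factor gene Xbp1 (-0.41, SE 0.0876), the stress-response regulator Atf4 (-0.30, SE 0.0635), the constitutive chaperone gene Hspa8 (-0.34, SE 0.0781) and the cytosolic chaperone gene Hsp90aa1 (-0.32). Hspa8 stood at 1067 ± 188 CPM in PBS (SD, n = 8), 1085 ± 95.6 CPM in MCMV (SD, n = 6) and 869 ± 132 CPM in MHV68 (SD, n = 5). Adjusted over the list alone, 14 members were lower. Of 16 glucocorticoid-responsive genes, 14 lay below PBS and 2 fell, Plin4 and Cdkn1a, with 7 lower when adjusted over the list alone. PBS litter 1 stood highest in this list too (0.531, other PBS litters -0.171 to 0.157), MHV68 litter 18 (-0.00158) lay within the PBS range, and the list was still called without PBS litter 1 (camera adjusted p = 0.00515, preset correlation). The glucocorticoid-induced Tsc22d3 had a log2 fold change of -0.36 that did not pass (adjusted p = 0.0750, edgeR). The camera test with its preset correlation gave adjusted p = 2.5e-12 for the heat shock list and 1.9e-04 for the glucocorticoid list. Both calls were lost with adjusted p = 0.909 with an estimated correlation, and the glucocorticoid call also with the dam's number as a covariate at the preset correlation (adjusted p = 0.343).

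Genes of cholesterol synthesis moved the other way. 17 of the 20 tested members were higher in MHV68 litters and 4 rose. Among them, the lanosterol synthase gene Lss (GRCm38 chromosome 10, 76531588 to 76557138) was at 38.4 ± 5.43 CPM in PBS (SD, n = 8) and 47.3 ± 2.99 CPM in MHV68 (SD, n = 5), a log2 fold change of 0.37 (SE 0.0733), and Insig1, a feedback regulator of sterol synthesis, rose by 0.44. Adjusted over the list alone, 12 members were higher. The list means overlapped between the groups, at -0.0428 to 0.230 in MHV68 litters and -0.237 to 0.204 in PBS litters. They are in log2 CPM relative to the mean of all litters. PBS litters 1, 7, 14 and 25 (-0.0120, -0.0224, 0.0978 and 0.204) lay within the MHV68 range. MHV68 litters 22 and 24 (0.217 and 0.230) lay above every PBS litter. The list had adjusted p = 7.9e-08 in camera with the preset correlation, and adjusted p = 0.909 with an estimated correlation.

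Astrocyte, microglia and antigen presentation genes were on average higher in MHV68, from litters 18, 21 and 22. The list means of MHV68 litters 16 and 24 lay below the mean of the 19 litters (astrocyte -0.267 and -0.0758, microglia -0.100 and -0.198, antigen presentation -0.120 and -0.133 in log2 CPM). Of 14 astrocyte genes 12 were higher and 3 rose: the glutamate transporter gene Slc1a2 (0.37, SE 0.0884), the bicarbonate cotransporter gene Slc4a4 (0.44, SE 0.107) and the growth factor receptor gene Fgfr3 (0.31, SE 0.0713). Of 20 microglia genes 19 were higher and 1 rose, the lysophospholipid receptor gene Gpr34 (0.38, SE 0.0857), while P2ry12 (0.31, adjusted p = 0.0532) and the fractalkine receptor gene Cx3cr1 (0.20, adjusted p = 0.0934) did not pass in edgeR's test. Of 18 antigen presentation genes 17 were higher and 2 rose, the peptide transporter gene Tap1 (0.43, SE 0.0925) and Ciita, the master regulator of class II genes, which was near the floor at 0.135 ± 0.0663 CPM in PBS (SD, n = 8) and 0.246 ± 0.0656 CPM in MHV68 (SD, n = 5). The class I gene H2-K1 had a log2 fold change of 0.20 (adjusted p = 0.168, edgeR). Adjusted over the list alone, 5 astrocyte, 4 microglia and 2 antigen presentation genes were higher. Camera with the preset correlation gave adjusted p = 5.4e-04 for astrocytes, 4.5e-04 for microglia and 9.7e-04 for antigen presentation. With an estimated correlation the adjusted p values were 0.918, 0.973 and 0.951. At the preset correlation all 3 calls were lost with mean RIN as a covariate (camera adjusted p = 0.228, 0.260 and 0.532), and those of microglia and antigen presentation also with all 48 pups (0.481 and 0.191). The microglia call was lost without PBS litters 6 and 26 as well (0.145).

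4 further lists were called in camera with the preset correlation. Of 20 synaptic vesicle genes 17 were lower (adjusted p = 0.0147), with Rab3a at a log2 fold change of -0.23, Snap25 at -0.27 and Syp at -0.22. Of 24 nuclear genes of oxidative phosphorylation 21 were lower (adjusted p = 0.00161), with Ndufs3 at -0.17, Cycs at -0.15 and Uqcrfs1 at -0.15. All 13 cerebellar markers were lower (adjusted p = 0.0191), with Zic2 at -0.52, Zic1 at -0.67 and Il20rb at -1.38 (-1.65 to -0.20 in other settings), but only PBS litters 6 and 26 stood high (list means 2.82 and 2.34, other PBS litters -0.613 to -0.249, MHV68 litters -0.667 to 0.695), and without them the list turned to higher without a call (adjusted p = 0.665). 12 of 14 fibroblast and meningeal genes were higher (adjusted p = 0.0147), with Igf2 at 0.96, Lum at 0.37 and Slc6a13 at 0.55. No member of these 4 lists passed on its own over all genes, and adjusted over the list alone only 1 did, a lower synaptic vesicle gene. With an estimated correlation their adjusted p values were 0.951 for synaptic vesicles and 0.973 for the other lists. At the preset correlation, mean RIN as a covariate ended the calls of synaptic vesicles (camera adjusted p = 0.481), cerebellar markers (0.0546) and fibroblasts (0.803, with the direction turned to lower). The dam's number ended those of synaptic vesicles (0.266), oxidative phosphorylation (0.530) and fibroblasts (0.911), and the fit of all 48 pups those of synaptic vesicles (0.115), cerebellar markers (0.864) and fibroblasts (0.293). Without PBS litter 1 the calls of oxidative phosphorylation (0.197) and synaptic vesicles (0.0530) were lost. Among the lists without a call, 19 of 30 interferon-response genes were higher and 1 rose, Ddx60 (camera adjusted p = 0.119). The dopamine neuron list was not called either (adjusted p = 0.868), with 18 of 27 members lower and 1 risen, the transcription factor gene Sox6 (0.43). By fry, 0 of the 42 lists passed as moving in 1 direction (smallest adjusted p = 0.0766) and 12 passed as changed in either direction.

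None of the 9 dopamine panel genes given here passed in MHV68 against PBS. The monoamine oxidase genes Maoa and Maob had log2 fold changes of 0.22 (SE 0.084, adjusted p = 0.167) and 0.21 (adjusted p = 0.409). Th was at 62.2 ± 40.4 CPM in PBS (SD, n = 8) and 50.0 ± 28.2 CPM in MHV68 (SD, n = 5), a log2 fold change of -0.33 (SE 0.399). The dopamine transporter gene Slc6a3 had -0.15, the vesicular transporter gene Slc18a2 0.03, Ddc -0.10, the receptor genes Drd1 0.56 and Drd2 0.01, and the transcription factor gene Nr4a2 -0.25, with adjusted p between 0.408 and 0.983 in edgeR's test. Within a sex, Th, Slc6a3, Nr4a2 and Drd1 had log2 fold changes of -1.44, -1.43, -1.29 and 1.25 in MHV68 males and of -0.24, -0.11, 0.24 and -0.15 in MHV68 females, and none passed.

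RNA integrity (RIN) differed between these groups, with a litter mean of 9.51 ± 0.315 in MHV68 (SD, n = 5) and 9.16 ± 0.215 in PBS (SD, n = 8; exact two-sided permutation p = 0.0272). The 286 calls fell to 0 with mean RIN or with the dam's number as a covariate (2460 and 2317 genes at an unadjusted p under 0.05, against 3786), and DESeq2 called 1169. With all 48 libraries and the litter as a block in limma-voom, 52 genes passed. Leaving out 1 litter gave 0 genes without PBS litter 8 or MHV68 litter 22, 4 without MHV68 litter 24, 10 without PBS litter 7, 123 without PBS litter 9, 124 without PBS litter 1, 146 without MHV68 litter 18, 148 without MCMV litter 5, 157 without PBS litter 26, 188 without MCMV litter 11 and 190 without PBS litter 14. Without PBS litters 6 and 26, whose sums held cerebellar transcripts, 401 genes passed, 182 of them among the 286.

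The comparison of MCMV with PBS asked the same question for the betaherpesvirus. Dopamine neuron genes lay on average above PBS in the MCMV litter sums, a difference that rested on PBS litters 6 and 26, and no single gene passed. Th was at 77.5 ± 24.3 CPM in MCMV (SD, n = 6) and 62.2 ± 40.4 CPM in PBS (SD, n = 8), a log2 fold change of 0.58 (SE 0.369), and Slc6a3 at 168 ± 47.5 and 132 ± 87.9 CPM, a log2 fold change of 0.62 (SE 0.386). Their sign turned when all 48 libraries were summed per litter without a batch term (-0.09 for Th and -0.11 for Slc6a3). Within a sex, Th, Slc6a3, Slc18a2 and Ddc had log2 fold changes of -0.24, -0.20, -0.28 and -0.23 in MCMV females and of 1.08, 1.02, 0.61 and 0.65 in MCMV males, and none passed. The other panel genes had log2 fold changes of 0.42 for Slc18a2, 0.39 for Ddc, -0.41 for Drd1, 0.24 for Drd2, 0.07 for Maoa, 0.13 for Maob and -0.02 for Nr4a2. edgeR's quasi-likelihood test called 0 of 20647 genes, with 801 at an unadjusted p under 0.05 and a smallest adjusted p of 0.989, and DESeq2 also called 0.

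The genes with the smallest p values in MCMV against PBS, none of which passed, were small differences with 1 exception. Higher in MCMV were Tonsl (0.23), a replication repair gene, the neuronal repressor gene Scrt1 (0.18), Olfml1 (0.23), the exchange factor gene Mcf2 (0.23) and Pcnx3 (0.15). Lower were Upf3b (-0.19), which acts in nonsense-mediated decay, Pura (-0.24), Zcchc3 (-0.16), Mblac2 (-0.20) and Lcn2. Lcn2, a siderophore-binding protein of innate immunity (ENSMUSG00000026822.14; GRCm38 chromosome 2, 32384633 to 32388252), was at 1.96 ± 1.93 CPM in PBS (SD, n = 8), 0.206 ± 0.103 CPM in MCMV (SD, n = 6) and 0.172 ± 0.210 CPM in MHV68 (SD, n = 5), a log2 fold change of -3.17 (SE 0.834) in MCMV. All of these had an adjusted p of 0.989 in edgeR's test. On simulated counts of this comparison, the test found 22.5% of genes changed 1.2-fold, 71% of those changed 1.5-fold and 94% of those changed 2-fold. The shares are averages over genes with a mean of at least 1 CPM. They may not hold for genes with a wide spread between litters, such as Th (SE 0.369) and Slc6a3 (SE 0.386).

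12 of the 42 lists were called in MCMV against PBS by camera with the preset correlation, 9 higher and 3 lower, and none of their members passed over all genes. All 12 calls were lost with an estimated correlation, with adjusted p = 0.654 for 10 lists and 0.807 for the ribosome and oxidative phosphorylation lists. At the preset correlation 2 of the 12 stayed without PBS litters 6 and 26, whose sums held cerebellar transcripts: oligodendrocyte precursors (camera adjusted p = 0.0282) and reactive astrocytes (0.0109). The other 10 were lost, among them dopamine neurons (0.0553), myelin (0.327), ependyma (0.943) and cerebellar markers (0.397, turned to higher). PBS litters 6 and 26 lay at -0.609 and -1.24 in the mean of the dopamine neuron list, with the other 6 PBS litters at an average of 0.228 and the MCMV litters at 0.225. In the myelin list the other PBS litters averaged 0.0810 and the MCMV litters 0.0847. Of 27 dopamine neuron genes 21 were higher (median log2 fold change 0.33, adjusted p = 2.3e-05), among them the receptor genes Ret (0.46) and Chrna6 (0.51), while Calb1 was lower (-0.48). All 10 oligodendrocyte precursor genes were higher (adjusted p = 2.3e-05), with Vcan at 0.14, Pdgfra at 0.14 and Ptprz1 at 0.15, and so were all 18 myelin genes (adjusted p = 1.0e-04), with Myrf at 0.21, Mal at 0.19 and Mog at 0.14. Of 20 cholesterol genes 19 were higher (adjusted p = 7.6e-04; Lss 0.11, Sqle 0.09), as were 25 of 26 cytosolic ribosome genes (adjusted p = 0.00153; Rps6 0.11, Rpl3 0.11, Rps3 0.10) and 9 of 9 ependymal genes (adjusted p = 0.00212; Rarres2 0.38, Foxj1 0.22, Hydin 0.39). The oxidative phosphorylation list (22 of 24 higher, adjusted p = 0.0213; Cycs 0.07, Ndufs1 0.06, Ndufb8 0.09), the astrocyte list (10 of 14, adjusted p = 0.0240; Fgfr3 0.19, Aldh1l1 0.14, Slc4a4 0.14) and the dopamine turnover list (10 of 11, adjusted p = 0.0323; Aldh1a1 0.19, Maob 0.13, Pts 0.08) were the other higher lists.

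The 3 lower lists in MCMV were cerebellar markers (13 of 13 lower, adjusted p = 7.6e-04; Neurod1 -1.18, Il20rb -1.17, Etv1 -0.29, which rose to 0.86, 0.76 and 0.24 with all 48 pups summed per litter), fibroblast and meningeal genes (14 of 14, adjusted p = 0.00380; Dcn -0.40, Slc6a13 -0.38, Aldh1a2 -0.30) and reactive astrocyte genes (10 of 15, adjusted p = 0.0361; Lcn2 -3.17, Timp1 -0.65, Vim -0.18). Adjusted over the list alone, 1 gene passed, Lcn2 in the reactive astrocyte list. At the preset correlation, the fit of all 48 pups ended the calls of dopamine neurons (camera adjusted p = 0.154), dopamine turnover (0.184), reactive astrocytes (0.184) and oxidative phosphorylation (0.954). With 2 dissection components as covariates those of reactive astrocytes (0.0721), ependyma (0.0721), fibroblasts (0.0819), oxidative phosphorylation (0.144) and ribosomes (0.144) ended, and with the dam's number that of oxidative phosphorylation (0.0720). By fry 0 lists passed as moving in 1 direction (smallest adjusted p = 0.805) and 0 as changed in either direction. The interferon response (adjusted p = 0.308) and microglia (adjusted p = 0.0859) lists were not called by camera with the preset correlation. RIN was 9.14 ± 0.235 in MCMV litters (SD, n = 6) against 9.16 ± 0.215 in PBS litters (SD, n = 8; exact two-sided permutation p = 0.950).

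**Figure D2:**
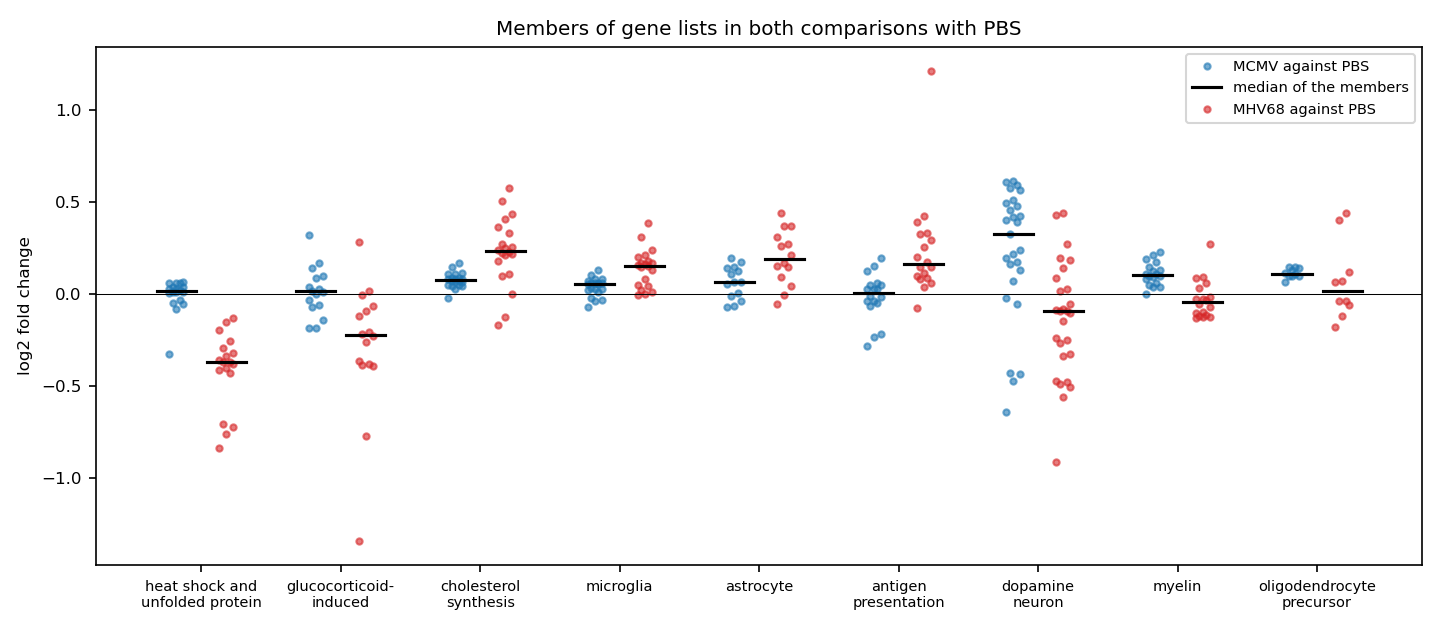
Log2 fold changes against PBS of the members of 9 gene lists, in MCMV litters (n = 6) and in MHV68 litters (n = 5) against 8 PBS litters, with a point per gene and a line at the median. The median of the heat shock and unfolded protein list was -0.37 in MHV68 and 0.02 in MCMV, and that of the dopamine neuron list -0.09 and 0.33.

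MCMV and MHV68 litters were compared directly to ask whether the offspring of the 2 infections differed from each other. 5 genes passed. Tnfrsf12a was at 12.4 ± 2.34 CPM in MCMV (SD, n = 6) and 5.93 ± 1.11 CPM in MHV68 (SD, n = 5), a log2 fold change of 1.13 (SE 0.179, adjusted p = 0.0384 in edgeR's test). Itpk1, an inositol phosphate kinase gene (ENSMUSG00000057963.9; GRCm38 chromosome 12, 102568582 to 102704930), was higher in MCMV by 0.41 (SE 0.0602, adjusted p = 0.0234). Lower in MCMV were the pericyte receptor gene Pdgfrb (-0.44, SE 0.0602; 28.5 ± 2.95 against 37.8 ± 3.66 CPM), the xylosyltransferase gene Xylt1 (-0.38, SE 0.0603) and the zinc exporter gene Slc30a1 (-0.36, SE 0.0521).

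Next in p value, without passing, were Plin4 (1.31, adjusted p = 0.0503), Fbxw23 (1.09), the chaperone activator gene Ahsa2 (0.37), the microtubule-binding gene Map7 (0.25) and Rtkn (0.29) on the higher side. On the lower side were Zdhhc15 (-0.39), Slitrk2 (-0.41), Wdfy4 (-0.62), March1 (-0.32) and the cholesterol exporter gene Abca1 (-0.41), with adjusted p between 0.0627 and 0.0798 in edgeR's test for these 9 genes. In the panel, Th had a log2 fold change of 0.90 (adjusted p = 0.304), Slc6a3 0.76, Slc18a2 0.39, Ddc 0.50, Drd1 -0.97 (adjusted p = 0.220), Drd2 0.22, Maoa -0.16, Maob -0.08 and Nr4a2 0.23, and none passed. Over all genes, 3154 had an unadjusted p under 0.05.

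12 lists were called between MCMV and MHV68 by camera with the preset correlation, 6 higher and 6 lower in MCMV, and all 12 calls were lost with an estimated correlation. The higher lists were heat shock and unfolded protein (17 of 18 members higher, adjusted p = 2.0e-13; Xbp1 0.42, Hspa8 0.35, Hspb1 0.87), oxidative phosphorylation (22 of 24, adjusted p = 1.0e-06; Cycs 0.22, Ndufs3 0.19, Sdhb 0.14), glucocorticoid response (15 of 16, adjusted p = 5.4e-06; Plin4 1.31, Tsc22d3 0.51, Sgk1 0.54), myelin (16 of 18, adjusted p = 9.3e-04; Mal 0.31, Myrf 0.23, Sox10 0.22), dopamine neuron (21 of 27, adjusted p = 0.00241; Lmx1a 1.41, Sox6 -0.30, Vip -0.88) and blood (6 of 6, adjusted p = 0.0193; Hba-a2 1.41, Hbb-bt 0.95, Hbb-bs 0.96). The lower lists were fibroblast and meningeal (13 of 14 lower, adjusted p = 6.5e-06; Slc6a13 -0.93, Aldh1a2 -0.72, Igf2 -1.13), cholesterol (17 of 20, adjusted p = 2.3e-04; Lss -0.25), antigen presentation (17 of 18, adjusted p = 4.0e-04; Tap1 -0.38, Ciita -1.02, Cd74 -0.51), microglia (15 of 20, adjusted p = 0.0117; Gpr34 -0.32, P2ry12 -0.25, Cx3cr1 -0.18), axon guidance (20 of 24, adjusted p = 0.0212; Dcc -0.51, Unc5d -0.51, Efnb2 -0.50) and astrocyte (10 of 14, adjusted p = 0.0367; Slc1a2 -0.36, Slc4a4 -0.30, Sox9 -0.19). None of these genes passed over all genes. In the dopamine neuron list MHV68 litter 18 stood apart at a mean of -1.14. The other MHV68 litters lay at -0.253 to 0.221 and the MCMV litters at -0.164 to 0.479. Litter 18 also had the highest cerebellar list mean of the MHV68 litters (0.695). Within these 12 lists, adjusted over the list alone, 14 heat shock, 4 glucocorticoid, 1 oxidative phosphorylation and 1 cholesterol gene were higher, and 5 cholesterol, 2 fibroblast, 2 antigen presentation, 2 axon guidance, 1 microglia and 1 astrocyte gene were lower.

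With an estimated correlation the adjusted p was 0.540 for the heat shock and glucocorticoid lists, 0.888 for microglia and 0.776 for the other lists. At the preset correlation, mean RIN as a covariate ended the calls of cholesterol (camera adjusted p = 0.608), antigen presentation (0.578), fibroblasts (0.279), microglia (0.880), astrocytes (0.991) and blood (0.355). The dam's number ended those of glucocorticoid response (0.224), oxidative phosphorylation (0.0995), cholesterol (0.241), fibroblasts (0.204) and blood (0.995), and the fit of all 48 pups those of axon guidance (0.499), astrocytes (0.680), blood (0.354) and microglia (0.621, with the direction turned). Without PBS litter 1 the blood call was lost (0.0713). By fry 0 lists passed as moving in 1 direction (smallest adjusted p = 0.0873) and 9 as changed in either direction. The 5 called genes fell to 0 with mean RIN (litter means 9.14 in MCMV and 9.51 in MHV68, exact two-sided permutation p = 0.0519) or the dam's number as a covariate, and to 1 with all 48 libraries and the litter as a block in limma-voom, while DESeq2 called 559. Leaving out 1 litter gave 0 genes without MCMV litter 10, 12 or 15 or MHV68 litter 16 or 22, 1 without MCMV litter 3, 3 without PBS litter 8, 14 or 25, MCMV litter 5 or MHV68 litter 21 or 24, and 8 without PBS litter 6.

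The log2 fold changes of the 2 infections against PBS were compared over all 20647 genes, which share the PBS litters. The correlation across genes was 0.43, and simulated unchanged groups against the same PBS litters gave 0.41 (0.39 to 0.43 over 20 simulations). The covariance was 0.0264 against a simulated 0.0218 (0.0202 to 0.0229), a difference of 0.00465. The simulated genes varied independently of each other, so the simulated ranges cannot show whether this difference exceeds chance. The same sign was found for 61.7% of genes against a simulated 64.1%. With the PBS litters split so that each infection had its own controls, the median correlation over 24 splits was 0.05 (-0.20 to 0.20). The median covariance over these splits was 0.00427 (-0.0221 to 0.0151). Calls could not be compared, because MCMV against PBS called 0 genes.

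Within each sex, the same contrasts were fitted on 1 pup per litter to ask whether either sex alone showed a difference. edgeR's quasi-likelihood test called 0 genes in each of the 4 contrasts. In females, 377 of 18589 genes in MCMV against PBS and 2699 in MHV68 against PBS had an unadjusted p under 0.05, and in males 961 and 1671 of 18617. The smallest adjusted p was 0.176 in MHV68 females, 0.305 in MHV68 males, 0.747 in MCMV males and 0.999 in MCMV females. DESeq2 called 0 genes in MCMV females, 328 in MHV68 females, 1 in MCMV males and 82 in MHV68 males. Without PBS litter 26, edgeR called 1 gene in MHV68 females.

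Brothers and sisters of 16 litters (7 PBS, 5 MCMV and 4 MHV68; 32 libraries) were compared within litters, as a check of the sex labels and for sex-dependent effects of the infections. 12 of 19363 genes differed between males and females, 7 higher and 5 lower in males. The Y-linked genes Eif2s3y (translation initiation), Uty and Kdm5d (histone demethylases) and Ddx3y (an RNA helicase) had log2 fold changes of 7.74, 8.29, 7.97 and 8.23, with adjusted p from 2.1e-10 to 2.3e-09 in edgeR's test. The infection effect differed between the sexes for 0 genes in MCMV (876 at an unadjusted p under 0.05) and 0 genes in MHV68 (1409), and DESeq2 also called 0 and 0. Lcn2, which was higher in PBS males than in any other group of pups, did not pass in either test of the sex difference (log2 differences of -3.55, SE 1.01, adjusted p = 0.838, and -3.72, SE 1.40, adjusted p = 0.687). It averaged 4.09 ± 3.69 CPM in PBS males (SD, n = 7), 0.176 ± 0.132 CPM in PBS females (SD, n = 8), 0.230 ± 0.158 CPM in MCMV males (SD, n = 9) and 0.109 ± 0.0516 CPM in MHV68 males (SD, n = 6).

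**Figure D3:**
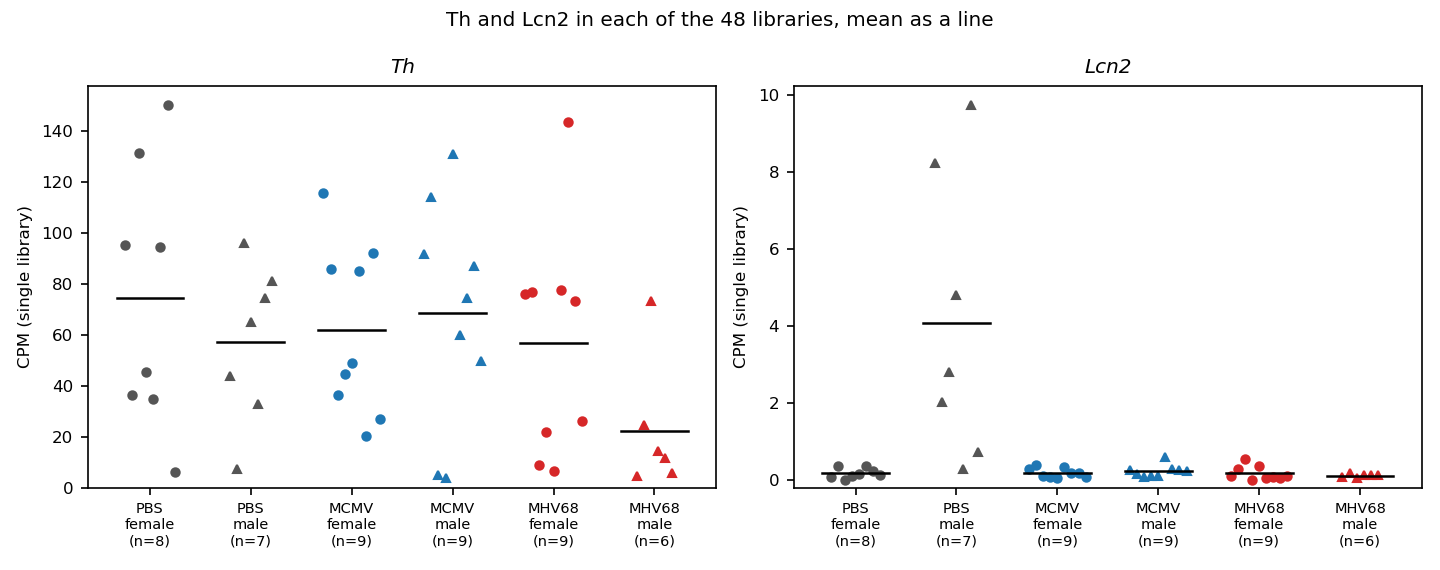
Expression in CPM (vertical axes) of Th and Lcn2 in each of the 48 libraries, by group of the dam and sex of the pup, with the group mean as a line. Th ranged from 3.76 to 150 CPM with overlap between all groups, and Lcn2 averaged 4.09 CPM in the 7 PBS males and at most 0.230 CPM in every other group of pups.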

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

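Of the tests in this part, the counts of other splits were planned before their results were seen, and the tests of RNA integrity, order of the dams, dissection, the left-out positions, the batch 4 libraries and the spread between litters were chosen after them. What the slope test of the dopamine genes can show was rewritten after its value was seen.

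Other splits of the litters into groups of the same sizes were fitted for each comparison. For MHV68 against PBS, 1 of 100 splits, the real one, gave as many genes (286, highest other 7). For MCMV against MHV68 it was 1 of 100 (5, highest other 3) and for male against female 1 of 30 (12, highest other 0). Random splits thus seldom gave such counts. The splits of litters between groups were not kept within batches, so they make chance unlikely and do not exclude it. Where the real count was 0 every split gives as many, so the splits decide nothing. This holds for MCMV against PBS (100 of 100 splits, highest other 1), for the contrasts within a sex (40 of 40 each) and for the sex differences of the MCMV and MHV68 effects (14 of 14 each, highest other 0), where the splits are also too few for a share under 0.05. Within a sex, the highest other split called 1627 genes in MCMV females, 114 in MHV68 females, 1 in MCMV males and 994 in MHV68 males, but only 2, 3, 1 and 2 of the other splits called any gene, and the median was 0. Splits that call so many genes point to a structure of the samples that does not follow the groups, and what it is was not tested.

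The 286 genes of MHV68 against PBS separated the groups by a mean score of 0.395 on the log2 scale. With RIN as a covariate the calls ended. The median SE of these genes went from 0.0705 to 0.0937, while their median absolute log2 fold change went from 0.334 to 0.337. With the dam's number both moved, to 0.0888 and 0.283. RIN differed between the groups and the genes were chosen on the same litters, so the stable fold change does not clear RIN. Positions of PBS and MHV68 litters between PBS at 0 and MHV68 at 1 were taken on genes chosen without the litter. The fits for this left out pairs of PBS or of MHV68 litters. Left-out MHV68 litters lay at a mean of 0.6254 (0.436 to 0.946) and left-out PBS litters at 0.254 (-0.00661 to 0.547). MCMV litters lay at 0.283 (0.177 to 0.397). MCMV litters were not in the contrast, but they stayed in these fits and entered the shared spread and the batch terms. Their positions, and the slopes below that use them, are therefore not on genes chosen without the litter. All 286 genes passed with 2 dissection components as covariates, which argues against the content that these components capture as the whole source. The components come from markers of neighbouring regions and may miss other tissue content, so dissection stays open. MHV68 litter 22, without which 0 genes passed, had the highest score (0.445). It also had the highest list means of dopamine receptor signalling (0.946) and of thalamus and hypothalamus (1.51). The other MHV68 litters scored 0.137 to 0.282 at dopamine receptor signalling means of -0.208 to -0.0553. The tables argue against a steady trend with the dam's number as the whole source. The slope on that number over the PBS and MCMV litters gives 0.0831 (SE 0.0438) of the left-out difference of 0.372. For this, PBS litters 25 and 26 were taken from the fit that left out both. A change late in the numbering of the dams stays open, although the sources used here do not say whether the numbers follow time. PBS litters 25 and 26, whose dam numbers are higher than those of the MHV68 litters, lay at a mean of 0.456 in the 1 fit that left out both. The 15 pairs of PBS litters without them lay at a mean of 0.185 (0.0322 to 0.400), and the 12 pairs with 1 of them at 0.110 to 0.4655. PBS litter 6 also lay high, at 0.448. Against the other PBS litters one by one (mean 0.186, SD 0.160, n = 6, 7 fits each) this is 0.615 (SE 0.298) of the way to the left-out MHV68 litters. Over all 7 fits of each of the 2 litters, most of which kept the other late litter in the choice, it is 0.380 of the way, so late order and infection cannot be told apart. The slope of RIN over the PBS and MCMV litters gives 0.0570 (SE 0.0712) of the 0.372, or 0.0240 (SE 0.0631) of 0.398 over all fits. The SE of each of these 2 values is larger than the value itself. The litters of the slope spanned a mean RIN of 8.9 to 9.45, and the MHV68 litters 9.15 to 10. The slope therefore cannot decide on RNA integrity, which stays open as a source. The infection itself stays open as a hypothesis. The libraries of batch 4 took no part in choosing the genes but come from the same dams. There the score averaged per litter was -0.0932 in MHV68 minus MCMV (3 and 4 litters, exact two-sided permutation p = 0.314 over 35 splits). It was -0.0271 without the male of MHV68 litter 24, which had the most Gabra6 of these libraries (180 CPM). A female of litter 16 (70.5 CPM) and a female and the male of litter 18 (33.9 and 26.5 CPM) also held Gabra6 and were kept. In batches 1, 2 and 3, on which the genes were chosen, the score difference was 0.310, 0.248 and 0.274.

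The dopamine neuron list was higher in MCMV than in PBS by camera with the preset correlation, at a median log2 fold change of 0.33, a call that was lost with an estimated correlation (adjusted p = 0.654). A permutation of the 6 MCMV and 8 PBS litters over the list's mean gave an exact two-sided p = 0.334, so the spread between litters could give such a difference. Neighbouring regions in the pieces stay open as a source. PBS litters 6 and 26, with the highest cerebellar list means (2.82 and 2.34), had the lowest dopamine list means of the PBS litters (-0.609 and -1.24, in log2 CPM relative to the mean of the 19 litters). The other 6 PBS litters averaged 0.228 and the MCMV litters 0.225. Without litters 6 and 26 the list's mean differed by -0.00341 in MCMV minus PBS (exact two-sided permutation p = 0.987). In the model without them the median log2 fold change was 0.122 and the preset-correlation call was lost (camera adjusted p = 0.0553). With 2 dissection components from markers of other regions as covariates the median stayed at 0.323 (median SE from 0.292 to 0.203) and the call stayed (adjusted p = 1.1e-07), so the tests do not agree. The fold change of the 27 genes followed each gene's slope on the rest of the list within groups (Pearson r = 0.876 and Spearman rho = 0.897 across genes, which are not independent replicates). This is what any shared shift in dopamine neurons between the groups would give, whether from the spread between litters, the cut or MCMV. The correlation therefore cannot tell these apart. Without litters 6 and 26 the list's mean left no difference for MCMV to explain, whereas the fit with dissection components did. The dopamine neuron content of the pieces and an effect of MCMV both stay open.

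Single litters stood apart from the others of their group in 20 of 345 groups tested over 115 genes, where chance gives about 5%. MCMV litter 10, MHV68 litter 18 and PBS litter 26 held 1 female library each, whereas every other litter summed 2 libraries, a brother and a sister. In MCMV litter 10, Pcnx3 was at 54.9 CPM (45.7 to 48.6 in the other MCMV litters), Zcchc3 at 9.71 CPM (10.9 to 11.4), Dcn at 43.8 CPM (19.96 to 25.5), Sqle at 60.9 CPM (74.7 to 79.1) and Tnfrsf12a at 17.1 CPM (10.8 to 12.4). Etv1 was at 55.8 CPM in MCMV litter 3 (63.3 to 67.0) and Slc7a11 at 61.1 CPM in MCMV litter 11 (34.9 to 43.8). In PBS litter 1, Rab3a was at 558 CPM (447 to 495 in the other PBS litters), Syp at 1726 CPM (1285 to 1398) and Sgk1 at 84.8 CPM (41.0 to 54.7). P2ry12 was at 27.4 CPM in PBS litter 7 (20.7 to 23.2), and PBS litter 26 had March1 at 32.4 CPM (24.2 to 27.8) and Vip at 13.1 CPM (1.23 to 6.04). In MHV68 litter 18, Lcn2 was at 0.546 CPM (0.0486 to 0.104 in the other MHV68 litters), Timp1 at 0.853 CPM (0.147 to 0.290) and Uqcrfs1 at 113 CPM (119 to 120). Calb1 was at 113 CPM in MHV68 litter 16 (79.1 to 82.7), Drd1 at 14.0 CPM in MHV68 litter 22 (3.26 to 4.84), and in MHV68 litter 21 the globin genes Hbb-bt and Hbb-bs were at 1.72 CPM (0.273 to 0.653) and 11.7 CPM (1.26 to 3.22).

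The most abundant marker of each of 6 lists of neighbouring regions, and Gabra6, were looked up in the libraries of batches 4 and 5, and 7 values lay above the highest PBS library. The batch 5 male of MCMV litter 5 had the cerebellar granule cell markers Gabra6 at 677 CPM (0 to 199 in PBS libraries) and Calb2 at 422 CPM (102 to 309). Slc17a7, a marker of cortical and cerebellar glutamate neurons, was at 1046 CPM in the batch 4 male of MCMV litter 10 and at 1145 CPM in the batch 4 female of MHV68 litter 18 (119 to 1002 in PBS libraries). That female also had Ttr at 1845 CPM (2.01 to 1694). The serotonin receptor gene Htr1a was at 29.6 CPM in the batch 4 male of MHV68 litter 18 and at 29.3 CPM in the batch 4 female of MHV68 litter 24 (8.01 to 26.4).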

How the results depend on the processing

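The settings with dissection components, with the dam's number, without PBS litters 6 and 26, without PBS litter 1 for the lists, and with only the litters of dams numbered 9 and above were chosen after the data were seen. No result turned its direction past the threshold. For MHV68 against PBS, the called genes were chosen on these same litters, so a kept sign was likely in advance. Sizes moved between the 15 other settings, from -0.95 to -0.21 for Hspb1 and from -1.54 to -0.97 for Plin4. All 16 genes named for the size of their change kept their sign in all 15 settings. All 286 called genes kept theirs with RIN or the dam's number, as did all 285 that were tested with only the later dams. Their number was 271 with RLE factors or without the female-only term, 1169 with DESeq2, 150 with no filter (38318 genes tested), 487 with a filter at 1 CPM (15127 tested), 61 with all 48 libraries as separate samples, 52 with all 48 in limma-voom and the litter as a block (correlation within litters 0.0147), 7 with all 48 summed per litter and 71 with no batch term. It was 496 with 1 surrogate variable, 1072 with 2 dissection components, 401 without PBS litters 6 and 26, and 0 with mean RIN, with the dam's number or with only the litters of dams numbered 9 and above (2460, 2317 and 1395 genes at an unadjusted p under 0.05). The number of genes or litters tested differed between settings and the SE was larger with RIN, but the cause was not tested. Leaving out 1 litter gave 0 (PBS litter 8 or MHV68 litter 22) to 404 genes (MCMV litter 10), with changes of over 1.5 times in 11 of 19 cases: also 4 (MHV68 litter 24), 10, 123, 124, 157 and 190 (PBS litters 7, 9, 1, 26 and 14), 146 (MHV68 litter 18), 148 and 188 (MCMV litters 5 and 11).

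The 5 genes of MCMV against MHV68 were 7 with RLE factors, 559 with DESeq2, 88 with 1 surrogate variable, 52 with 2 dissection components and 9 without PBS litters 6 and 26. They were 1 with all 48 libraries as separate samples or with the litter as a block, and 0 with all 48 summed per litter, with mean RIN, with the dam's number or with the later dams alone; the cause was not tested. Without 1 litter they ranged from 0 (MCMV litter 10, 12 or 15, MHV68 litter 16 or 22) to 8 (PBS litter 6), with 1 without MCMV litter 3 and 3 without PBS litter 8, 14 or 25, MCMV litter 5, or MHV68 litter 21 or 24.

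MCMV against PBS stayed at 0 genes in all 15 other settings and in all 19 fits without 1 litter. Within a sex, DESeq2 called 328 genes in MHV68 females, 1 in MCMV males and 82 in MHV68 males, and leaving out 1 litter gave 0 to 1 gene in MHV68 females (1 without PBS litter 26). Every other setting gave 0. Male against female gave 11 to 15 genes throughout, 13 without the replicate block by litter, and the sex differences of the infection effects stayed at 0, so the block changed no call there. All list calls went to 0 in the 3 comparisons with an estimated correlation and with fry. Without PBS litters 6 and 26 the 12 lists of MCMV against PBS fell to 3, 2 of them among the 12. The remaining settings gave between 7 and 15 called lists per comparison but exchanged many of them. Of the 10 lists of MHV68 against PBS, 4 kept their call with mean RIN, 5 with all 48 pups, 6 with the dam's number, 10 with 2 dissection components, 8 without PBS litters 6 and 26 and 8 without PBS litter 1. Of the 12 of MCMV against PBS these were 12, 8, 11, 7, 2 and 11, and of the 12 of MCMV against MHV68 6, 8, 7, 12, 12 and 11. 6 lists turned their direction without passing. Without PBS litters 6 and 26 these were cerebellar markers in MCMV against PBS (adjusted p = 0.397) and in MHV68 against PBS (0.665), where these 2 litters hold the cerebellar transcripts, and oxidative phosphorylation (0.917) and ribosome genes (0.977) in MCMV against PBS. The others were fibroblast and meningeal genes in MHV68 against PBS with mean RIN (adjusted p = 0.803) and microglia in MCMV against MHV68 with all 48 pups (adjusted p = 0.621). The cause was not tested.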

Other observations

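All tests of Lcn2 in this part were chosen after its values were seen, as were the genes named in the first paragraph, which belong to lists fixed earlier.

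Outside the lists that camera called, single genes rose in MHV68 litters in lists whose other members went both ways. Pdgfra, the growth factor receptor that marks oligodendrocyte precursors, rose by 0.40 on the log2 scale (SE 0.062) and Ptprz1, a receptor phosphatase of these cells, by 0.44 (SE 0.0786), while 5 of the 10 members of their list were higher and 5 lower. The pericyte receptor gene Pdgfrb rose by 0.41 (SE 0.0588), the neurotrophin receptor gene Ntrk2 by 0.32 (SE 0.0749), the guidance receptor gene Dcc by 0.60 and the alarmin gene Il33 by 0.31 (SE 0.0741), while 5 of 10 pericyte and smooth muscle genes, 9 of 20 neurotrophic genes, 16 of 24 axon guidance genes and 7 of 14 cytokine genes were higher. Their adjusted p in edgeR's test ran from 0.0178 for Pdgfra and Pdgfrb to 0.0491 for Il33. By fry, which here asked whether members of a list changed in either direction, the neurotrophic list had adjusted p = 3.0e-05, oligodendrocyte precursors 0.00178, endothelium 0.0182, cAMP signalling 0.0182, cytokines 0.0183, pericytes and smooth muscle 0.0292 and Parkinson genes 0.0486. None of these lists passed as moving in 1 direction. Fry does not ask whether the members changed more than other genes. Over all 20647 genes, 18.3% had an unadjusted p under 0.05 in MHV68 against PBS in edgeR's test. The fry values therefore do not show a change particular to these lists.

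Lcn2 was higher in the brother than in the sister in 7 of 7 PBS litters (exact two-sided sign-flip p = 0.0156, the smallest that 7 pairs can give), against 3 of 5 MCMV and 2 of 4 MHV68 litters. The brother minus sister difference was larger in PBS than in MCMV (exact two-sided permutation p = 0.0139) and than in MHV68 (p = 0.00909), without adjustment for the genes that were looked at, while edgeR's interaction tests did not pass. The tables argue against leukocytes in the sample as the source, since the 9 leukocyte genes that could be tested differed by a mean of 0.0820 on the log2 scale between PBS brothers and sisters and the general leukocyte gene Ptprc by 0.0949, against 3.38 for Lcn2, and against a single batch, since the smallest difference over the PBS litters of all 3 batches was 0.612. The neutrophil genes S100a8 (0.521, 6 of 7 brothers higher) and S100a9 (0.0663) were near the floor. The blood list differed by 0.417 (exact two-sided p = 0.344) and the choroid plexus list by 0.589 (p = 0.328, 5 of 7 brothers higher), which leaves these open. Reactive astrocytes stay open as a possible source, with a brother minus sister difference of 0.127 for the rest of that list (exact two-sided p = 0.484). No biological explanation of a rise in control males was tested.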
